A study of Mus musculus with 6 samples.

How the data were processed

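RNA was measured in 6 libraries of mouse primary cortical neurons, 3 untreated and 3 stimulated with NMDA, the agonist that gives the NMDA class of glutamate receptors its name. Per the labels' protocols, neurons from embryonic day 16 Swiss-Webster embryos were grown to day 13 in vitro, and the stimulated cultures received 50 µM NMDA for 10 minutes followed by 50 minutes in drug-free medium. Total RNA with an RNA integrity number of at least 8 was made into stranded poly(A)-selected libraries, which were sequenced from one end on a NextSeq instrument to a stated average of 35 to 45 M reads. The shared growth protocol also mentions etoposide, a topoisomerase II poison, but no library analysed here is labelled with it. The extract protocol speaks of 2 biological replicates while 3 samples are listed per group, so p-values measure the spread between these samples, part of which may be technical.

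The deposited table holds raw read counts per gene made by the authors, with Ensembl gene identifiers and mouse gene symbols. The submitters' processing notes name Trimmomatic, TopHat and HTSeq and the builds mm10 and GRCm38.p6; their versions, the annotation release and the strand setting of the counting are not given in the sources used here. The counts were whole numbers and their totals ranged from 15417234 in NMDA replicate 1 to 19183999 in control replicate 1. The table has 38293 rows, of which 23838 had a count in at least 1 library. A symbol was blank in 2153 rows, which held 0.219% to 0.246% of a library's counts; these rows stayed in the tests, 289 were named from the reference table and the others carry their identifier. Gene positions, lengths and classes came from GENCODE M21 on GRCm38, the assembly that mm10 also denotes, which held 36429 of the identifiers and 14489 of those tested.

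Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3: a default low-count filter (minimum count 10, minimum total 15) that left 14642 genes, TMM scaling, robust quasi-likelihood fits and F tests with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are counts scaled to library size and TMM factors, computed here from the deposited counts. A further count required a fitted change of at least 1.5-fold. The design, the alternatives, 31 gene lists and the rule for naming genes were fixed before the data were examined. That rule took the 12 largest rises and falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, 15 genes fixed by name, and list examples from the 4 members with the smallest p, in that order; genes outside it are said to be so. Lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry.

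The replicate numbers were checked for pairing before the fits were compared. Deviations from the group means correlated at 0.54, 0.38 and 0.49 between libraries of the same number, and every correlation between different numbers was negative, from -0.41 to -0.02. The deviations of 3 libraries from their mean cancel out for each gene. The negative values therefore follow in part from the positive ones and are no separate support. No p-value was computed for this match. All 3 exceeded the limit of 0.1, so the numbers were taken to pair the libraries; the pairing comes from the data, since the labels do not say what a number stands for. The edgeR fit with the replicate number as a block (2 residual degrees of freedom, against 4 without it) is given beside each result whose call it changes. The biological coefficient of variation was 13.0% without the block and 7.06% with it.

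Libraries of the same group differed far beyond sampling noise, with chi-square values of 8.17 to 59.0 per degree of freedom, so none was treated as a copy of another. Per-library measures were compared by two-sided exact permutation tests, which cannot give a p below 0.1 with 3 against 3 libraries. These tests treat the 6 libraries as exchangeable and ignore the pairing by replicate number. The scripts were tested on simulated counts drawn from these libraries' fitted means, pair effects and dispersions, with known changes put into some of the genes; 14486 genes passed the filter. Without the block, 15 of 66 genes changed 1.5-fold, 40 of 67 changed 2-fold and 57 of 63 changed 4-fold were called, and 0 of 112 calls were unchanged genes. With the block these were 55 of 66, 62 of 67 and 63 of 63, and 15 of 195 calls (7.69%) were unchanged genes.

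Alternatives were DESeq2 1.42.0 size factors, upper quartile scaling, the DESeq2 Wald test, limma-voom, no low-count filter, a filter of at least 1 CPM in all 3 libraries of a group, the block, and each library left out in turn. Offsets for GC content and exonic length (mgcv 1.9.3) and variants of the blocked fit were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Because the counting's strand setting is not given, reads of genes whose exons overlap on opposite strands cannot be told apart; among the genes named here this concerns Junb (with Prdx2), Cebpd (Spidr), Dusp5, Bhlhe40, Bdnf, Grin2b, Pds5a, Homer2, Kcnma1, Cdkn1a, Aldh1l1, Ccn2, Thbs1, Meg3 and Miat (each with a little-studied transcript), Cntnap1 (Plekhh3), Ccdc39 (Ttc14), Ctcf (Agrp), Top2b (Rarb), Top3b (Vpreb1), Dnaja1 (Smu1), Tagln (Pcsk7), Cacna1h (Tpsg1), Ryr3 (Aven), Vcl (Ap3m1) and Zyx (Epha1).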

Results

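Gene expression was measured by RNA-seq in mouse cortical neurons that were left untreated (control, 3 libraries) or stimulated with 50 µM NMDA for 10 minutes and collected after 50 minutes of recovery (3 libraries). The series concerns RNA polymerase II, DNA supercoiling and cohesin in neurons, and the comparison asks which transcripts differ within the first hour after glutamate receptor stimulation. Totals of counted reads were 19183999, 17860691 and 18395131 in control replicates 1, 2 and 3, and 15417234, 17787649 and 18606264 in NMDA replicates 1, 2 and 3.

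NMDA raised a set of activity-induced genes by large factors. Fosb rose most, from 1.04 ± 0.748 to 108 ± 29.0 CPM (mean ± SD, n = 3 per group), a log2 fold change of 6.68 ± 0.38 (SE), and Fos, which encodes another component of the AP-1 transcription factor, rose from 3.30 ± 0.573 to 116 ± 24.5 CPM (log2 5.13 ± 0.19). Npas4, a neuron-specific transcription factor induced by calcium entry, rose from 5.31 ± 1.19 to 64.2 ± 24.4 CPM, and Arc, which regulates AMPA receptor trafficking, from 3.79 ± 1.01 to 23.8 ± 9.11 CPM. The nuclear receptors Nr4a1 (log2 2.91 ± 0.12) and Nr4a2 (2.87 ± 0.12) rose more than 7-fold with little spread between libraries. Altogether 55 genes were higher and 8 lower at an edgeR adjusted p under 0.05 among 14642 tested. In all 63 the 3 NMDA libraries lay on the same side of the 3 controls, which selection at this threshold favours. Over all tested genes such separation held for 19.3%, against 10% by chance. The counts depended on the tool and on single libraries: DESeq2 called 149 higher and 157 lower, edgeR without a filter 130 and 130, and limma-voom 53 and 7. Leaving out control replicate 1, 2 or 3 gave 35, 19 or 40 higher and 1, 1 or 2 lower, leaving out NMDA replicate 1 gave 89 and 57, and leaving out NMDA replicate 2 or 3 gave 38 or 42 higher and 0 lower. Among the genes named in this paragraph, Arc lost its call without control replicate 1 or 2.

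The 12 largest rises also included the transcription factor genes Egr2 (log2 3.30), Junb (3.24), Maff (3.21), Atf3 (3.01) and Cebpd (2.30), and Ccn1, a secreted matrix protein (2.55). The edgeR adjusted p of the 12 ranged from 3.23e-06 for Fos to 0.0062 for Cebpd, which lost its call without control replicate 2, while Ccn1 lost it without control replicate 3 and without a filter. On GRCm38, Fosb (ENSMUSG00000003545) lies on chromosome 7 from 19302696 to 19310051, Fos (ENSMUSG00000021250) on chromosome 12 from 85473890 to 85477273, Npas4 (ENSMUSG00000045903) on chromosome 19 from 4984355 to 4990316 and Arc (ENSMUSG00000022602) on chromosome 15 from 74669083 to 74672570. Egr1, fixed by name, rose from 37.6 ± 6.38 to 152 ± 14.7 CPM (adjusted p = 0.00012). Bdnf, which encodes a neurotrophin, was at 14.7 ± 4.05 CPM in control and 19.5 ± 1.92 CPM in NMDA libraries (log2 0.41 ± 0.18, adjusted p = 0.37) and did not pass.

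**Figure D1:**
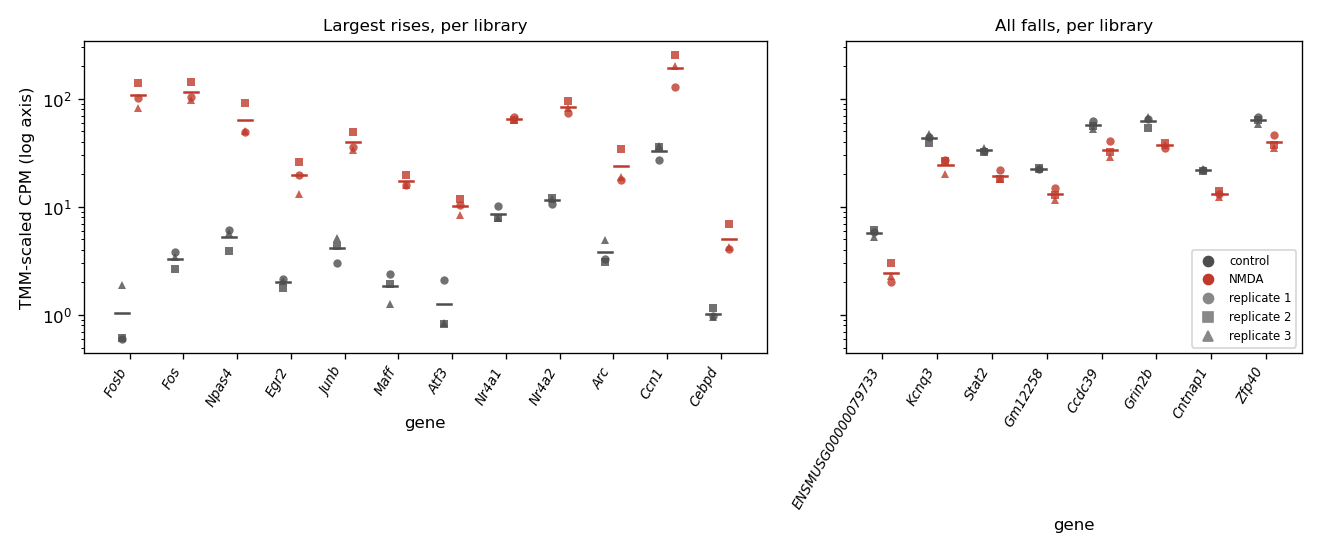
TMM-scaled CPM per library, on a log axis, of the 12 largest rises and of all 8 falls; symbols mark the replicate number, grey is control, red is NMDA and bars are means of 3 libraries. The NMDA libraries lie above the controls for each rise and below them for each fall, as the rule for naming genes required.

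The rapid activity-induced list, genes that neurons transcribe within minutes of stimulation, had 21 of 32 members higher and none lower, with a median log2 change of 1.75. Adjusted over the list alone, 28 were higher, and with the replicate block 28 were. Fos, Nr4a1, Egr1 and Junb had its smallest p. Of the delayed list, genes with slower kinetics, 9 of 27 rose, among them Nr4a2, Nr4a3 (log2 1.58), Homer1 (1.13), which encodes a postsynaptic scaffold protein, and Nfil3 (1.22); 14 were higher adjusted over the list alone and 16 with the block. MAP kinase feedback inhibitors, which dampen MAP kinase signalling, had 4 of 15 higher, namely Dusp6 (1.02), Spry4 (0.73), Dusp5 (1.67) and Spry2 (0.56), and 10 with the block (11 adjusted over the list alone). Without control replicate 2 all 4 lost their call, as did Homer1 and Nfil3, and Spry2, Spry4 and Dusp5 also lost it without other libraries. Camera called these 3 lists (adjusted p = 2.52e-166, 7.14e-39 and 1.05e-16). With an estimated correlation the rapid and feedback lists kept their call (adjusted p = 0.012 for each) and the delayed list did not (adjusted p = 0.067). In the blocked fit none of the 3 did (adjusted p = 0.23 for the rapid, 0.44 for the delayed and 0.23 for the feedback list). Fry called all 3 without the block (adjusted p = 0.0053, 0.028 and 0.00096). With the block fry called the rapid and feedback lists (adjusted p = 0.042 and 0.040) and not the delayed list (adjusted p = 0.11).

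Clock genes had 2 of 15 members higher, Per1 (log2 1.26 ± 0.14, from 25.5 ± 4.27 to 61.0 ± 7.15 CPM), a light- and CREB-responsive period gene, and Bhlhe40 (0.82 ± 0.11), a repressor of the clock loop, which lost its call without control replicate 2. Adjusted over the list alone 3 were higher. The list was called by camera (adjusted p = 0.0032) and not with an estimated correlation (adjusted p = 0.42). Fry did not call it without the block (adjusted p = 0.14) and called it with the block (adjusted p = 0.040). With the block 4 were higher and 1, Clock (-0.25), lower.

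The 8 genes that fell did so by less than the leading rises. They included Grin2b, the GluN2B subunit of the NMDA receptor itself, which fell from 62.7 ± 7.89 to 37.2 ± 1.87 CPM (log2 -0.75 ± 0.11, adjusted p = 0.016), and Kcnq3, a subunit of the M-type potassium channel, which fell from 43.6 ± 4.13 to 24.7 ± 3.75 CPM (-0.82 ± 0.13, adjusted p = 0.027). Stat2, a transducer of interferon signals, fell from 33.5 ± 1.30 to 19.5 ± 2.35 CPM (-0.78 ± 0.11). The others were Cntnap1 (-0.74), which encodes a protein of axo-glial junctions, Zfp40 (-0.68), Gm12258 (-0.78), Ccdc39 (-0.76), whose exons overlap those of Ttc14 on the opposite strand, and the unnamed ENSMUSG00000079733 (-1.22). At least 1.5-fold, 52 genes were higher and 8 lower. All 8 lost their call without control replicate 1, without control replicate 3, without NMDA replicate 2 and without NMDA replicate 3, taken in turn, and all but Grin2b without control replicate 2; ENSMUSG00000079733 also lost it without NMDA replicate 1.

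Within pairs of the same replicate number many more genes passed: 828 were higher and 1223 lower, and 130 and 337 at least 1.5-fold. DESeq2 with the same block called 433 higher and 530 lower (100 and 186 at least 1.5-fold) and shared 955 of the 2051 calls. All 63 calls made without the block were among the 2051 in the same direction. Of the 828, 816 moved the same way in all 3 pairs, as did 1216 of the 1223, which selection by a paired test favours. With offsets for GC content and length added after the data were seen, the blocked split turned to 1138 higher and 959 lower. The median log2 change of all tested genes moved from -0.0036 to 0.023 with these offsets. With DESeq2 size factors and the block that median was 0.0065, and 926 were higher and 1151 lower. A move of the zero point is thus not separated from the turn. Without both libraries of replicate 1, 1341 were higher and 1366 lower, without those of replicate 2, 335 and 683, and without those of replicate 3, 705 and 758.

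Genes for receptors and channels lay on the lower side. Of 22 glutamate receptor subunits, 1 fell without the block and 5 with it: Grin2b, Grin2a (-0.84 ± 0.14 within pairs), Gria4 (-0.31), Grik2 (-0.37) and 1 more; 3 were lower adjusted over the list alone. Potassium channels had 1 of 25 lower, Kcnq3, and 11 lower and 1 higher within pairs, including Kcnb2 (-0.70), Kcnma1 (-0.61) and Kcnt1 (-0.95); 6 were lower adjusted over the list alone. Of 28 synaptic adhesion and scaffold genes none passed without the block (4 lower adjusted over the list alone), while 8 fell and 1 rose within pairs, with Dlg2 (-0.47), Dlgap2 (-0.52), Homer2 (-0.38) and Camk2a (-0.39) among those that fell. Camera called all 3 lists (adjusted p = 0.0037, 1.05e-05 and 0.037), and none with an estimated correlation (adjusted p = 0.49, 0.42 and 0.82). Other splits of the same 6 libraries gave 9 to 15 list calls at the preset correlation, against 12 for NMDA and control. Every other split mixes the groups unequally on each side, so part of any NMDA effect remains in it. Only the number of lists was compared, not which lists were called. Such a call alone therefore does not tie these 3 lists to NMDA, and the splits do not decide it. The synaptic list lost its call without control replicate 1 or 3 or NMDA replicate 2 or 3, and the glutamate receptor list without control replicate 3. With the block and GC and length offsets the synaptic list also lost its call, and its median turned from -0.046 to 0.020. The median of all tested genes was 0.023 in that fit. Markers of astrocytes rose in the same blocked fit, with mean changes of 0.16, 0.38 and 0.30 in pairs 1, 2 and 3. Neuron markers had no matching fall. Their mean changes in pairs 1, 2 and 3 were 0.25, -0.02 and -0.01 for excitatory and 0.06, 0.0036 and 0.20 for inhibitory markers. A lower share of neurons is thus not seen in these markers, though a shift in the share of cell types is not fully separated from these falls.

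**Figure D2:**
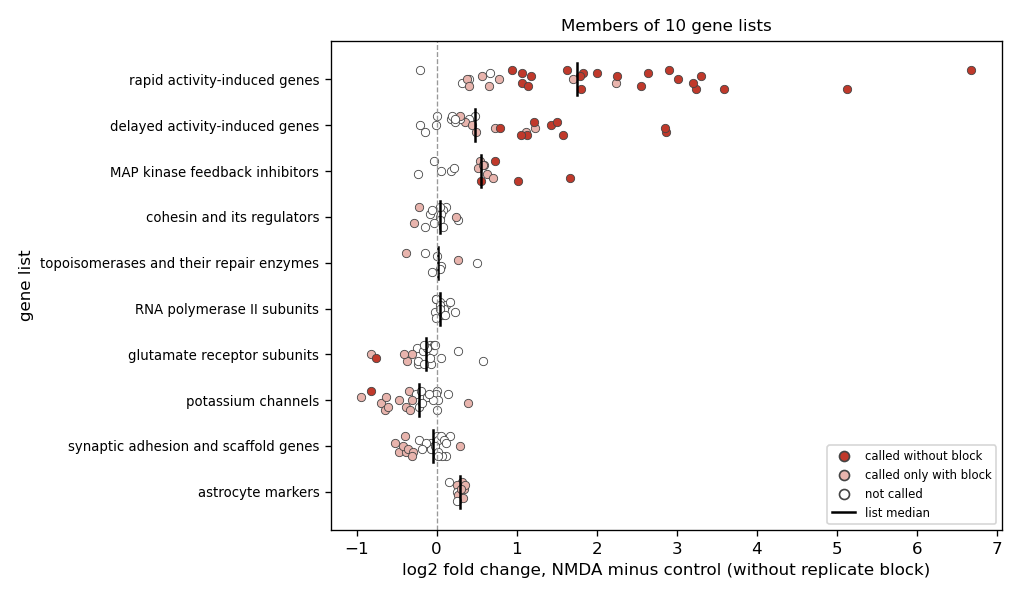
Log2 fold change (NMDA minus control, fit without the replicate block) of each tested member of 10 gene lists; dark points passed without the block, pale points only with it, open points in neither, and black bars are medians. The median is 1.75 for the rapid activity-induced list and 0.05 for cohesin and its regulators.

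No listed transcript of the machinery named in the series title passed without the block. That fit called 15 of 66 simulated 1.5-fold changes, so changes of that size can be missed. Within pairs some passed, beside 2051 of all 14642 tested genes. Of 15 genes for cohesin and its regulators, 0 passed in edgeR without the block, also adjusted over the list alone, and the median log2 change was 0.05 (camera adjusted p = 0.96). At an unadjusted p under 0.05 edgeR found 2, and DESeq2 and limma-voom called 0. Smc1a, a core subunit of the cohesin ring, was at 94.6 ± 13.1 CPM in control and 112 ± 7.15 CPM in NMDA libraries (log2 0.24 ± 0.11, adjusted p = 0.37) and passed within pairs (0.25 ± 0.07). Mau2 (-0.28), part of the cohesin loader, and Pds5a (-0.22), which binds the ring, fell within pairs. Values without the block were 0.05 ± 0.10 for Smc3, 0.06 ± 0.10 for Rad21, -0.14 ± 0.08 for Nipbl, 0.05 ± 0.08 for Wapl and 0.07 ± 0.08 for Ctcf, and none of the 5 passed in either fit.

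Among 8 topoisomerases and their repair enzymes 0 passed without the block, and 1 rose and 1 fell within pairs. These were Top1, which relaxes supercoils ahead of and behind polymerase, at 182 ± 25.8 CPM in control and 218 ± 17.7 CPM in NMDA libraries (0.27 ± 0.07 within pairs), and Top3b (-0.37 ± 0.08). Top2b, the topoisomerase II of neurons, stood at 0.04 ± 0.09 (adjusted p = 0.87). None of 13 RNA polymerase II subunits passed in either fit, with Polr2a, the largest subunit, at 132 ± 6.08 CPM in control and 131 ± 9.88 CPM in NMDA libraries. Of 25 pausing and elongation factors 0 passed without the block, and within pairs Rtf1 (0.33), Aff1 (0.56) and Larp7 (0.50) rose and Ccnt2 (-0.44), a cyclin of the elongation kinase P-TEFb, fell. At an unadjusted p under 0.05 edgeR found 3, 0 and 4 in these 3 lists, DESeq2 and limma-voom called 0 in each, and camera called none of them (adjusted p = 0.77, 0.34 and 0.15).

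Stress and metabolic lists had no member past the threshold without the block; adjusted over the list alone, 1 heat shock gene was higher and 1 lower, and 1 histone gene was lower. DESeq2 called 1 apoptosis gene and no other member of these lists, and limma-voom none. Within pairs, 5 of 21 apoptosis and p53 target genes rose, among them Mcl1 (0.38), a survival factor of the Bcl-2 family, the pro-apoptotic Pmaip1 (0.62) and the cell cycle inhibitor Cdkn1a (0.48). Of 13 heat shock genes 3 rose within pairs, Dnajb1 (0.33), Dnaja1 (0.31) and Hsp90aa1 (0.32), and their regulator Hsf1 fell (-0.51). Ribosomal protein genes (median 0.08, 80 tested, 1 higher within pairs) and nuclear-encoded respiratory chain subunits (0.07, 76 tested, 4 higher within pairs) shifted slightly upwards. Camera called these 4 lists (adjusted p = 0.0093, 0.0032, 0.0043 and 0.0023), and none with an estimated correlation (adjusted p = 0.25, 0.42, 0.82 and 0.82). Fry called the apoptosis list (adjusted p = 0.032, and 0.040 with the block) and none of the others in either fit. The ribosomal list lost its call without NMDA replicate 1 and without control replicate 3, where its median was -0.044, and with the block and GC and length offsets, and the respiratory list without control replicate 3.

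The other lists were not called by camera without the block. Endoplasmic reticulum stress genes (16 tested, adjusted p = 0.10) had 3 higher and 1 lower within pairs, cholesterol synthesis genes (18 tested, adjusted p = 0.088; called within pairs at the preset correlation and not with an estimated one, adjusted p = 0.68) had 3 higher, histone acetylation enzymes (18 tested, adjusted p = 0.38) had 2 lower, double-strand break repair genes (13 tested, adjusted p = 0.89) had 1 lower, Atm (-0.31), and replication-dependent histones (10 of 52 tested, adjusted p = 0.87) had 1 lower. No member of the inflammatory list (6 of 14 tested, adjusted p = 0.34) or of the mitochondrially encoded genes (12 tested, adjusted p = 0.72) passed in either fit.

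Among markers of cell types, those of astrocytes shifted upwards. None of the 10 passed without the block, 7 rose within pairs, among them Aldoc (0.26), Aldh1l1 (0.33) and Sox9 (0.31), and the median was 0.29 (camera adjusted p = 0.0038, and 0.49 with an estimated correlation), with the call lost without NMDA replicate 3. At an unadjusted p under 0.05 edgeR found 2 of the 10, and DESeq2 and limma-voom called none. The mean change of oligodendrocyte markers was -0.26, -0.09 and 0.15 in pairs 1, 2 and 3. Excitatory (10 tested) and inhibitory (13 tested) neuron markers had medians of -0.01 and 0.11, with 2 and 1 members higher within pairs (1 and 0 without the block, adjusted over the list alone); the mean of the excitatory markers was 0.07, of the other sign than their median. Fibroblast and mural markers (8 tested) had 2 higher within pairs, Tagln (0.67) and Acta2 (0.56), progenitor and cycling markers (11 tested) had 3 higher, including Nes (0.37) and Sox2 (0.22), and oligodendrocyte markers (6 tested) had 1 lower, Mog (-0.65). No marker of oligodendrocyte precursors (5 tested), microglia (3 of 11 tested) or endothelium (2 of 6 tested) passed. These 8 other marker lists were not called by camera, with adjusted p from 0.15 to 0.98.

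Expression of long genes relative to short genes was compared per library, by a test that ignores the pairing and whose smallest possible p is 0.1. The median log2 CPM of 2245 genes with bodies over 100 kb exceeded that of 6344 genes under 20 kb by 1.30 ± 0.10 in control and 1.27 ± 0.02 in NMDA libraries (SD, n = 3; two-sided exact permutation p = 0.8), with differences within pairs of 0.08, -0.0039 and -0.16. Across genes, which are not independent replicates, the rank correlation of the log2 fold change with gene body length was -0.07. Within pairs, 7.59% of genes under 10 kb were called higher and 5.35% lower, against 3.57% and 10.7% of genes over 200 kb, and the median gene body was 17.8 kb for genes called higher and 28.7 kb for genes called lower. Across genes, the blocked log2 fold change had rank correlations of -0.07 with gene body length, -0.18 with exonic length and 0.14 with GC content, so the gradient over gene bodies is not separated from those properties. Mitochondrially encoded genes took 14.0 ± 3.96% of counts in control and 12.8 ± 2.25% in NMDA libraries (exact permutation p = 0.7), and the 10 most abundant genes 13.1 ± 3.74% and 11.9 ± 2.12% (p = 0.7 by the same permutation test). Genes detected numbered 20028 ± 263 in control and 19656 ± 62.1 in NMDA libraries, with every NMDA library below every control. The exact permutation p, which ignores the pairing, was 0.1, the smallest that test allows. The difference of -373 genes became -231 without control replicate 1, and was -727 in pair 1, where the total counts also differed most, -293 in pair 2 and -98 in pair 3.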

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

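Alternatives to the blocked fit, its offsets and the pairs left out were chosen after seeing the data; the other settings were fixed before the data were examined. Counts of genes higher and lower were 55 and 8, and 52 and 8 at least 1.5-fold. They became 149 and 157 (87 and 108) with DESeq2, 130 and 130 (82 and 78) without a filter, 828 and 1223 (130 and 337) with the replicate block, and 1138 and 959 (143 and 309) with the block and GC and length offsets; DESeq2 size factors gave 5 lower in either count. Leaving out a library gave 19 to 89 higher and 0 to 57 lower (19 to 81 and 0 to 52 at least 1.5-fold). Of the 63 calls, 60 were shared with DESeq2 size factors, upper quartile scaling and limma-voom, all 63 with DESeq2, the strict filter and the block, and 20 without control replicate 2. Within pairs, DESeq2 with the block gave 433 higher and 530 lower (186 lower at least 1.5-fold), and leaving out a pair gave 335 to 1341 higher and 683 to 1366 lower. The cause of these differences was not tested.

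Camera called 12 of 31 lists, 2 with an estimated correlation, and fry 4, which were the rapid, delayed, feedback inhibitor and apoptosis lists. The replicate block changed the camera call of cholesterol synthesis genes, which was not held with an estimated correlation (adjusted p = 0.68), and of no other list at the preset correlation. With the block and GC and length offsets camera called 11, gaining the cholesterol list and losing the ribosomal protein list and the synaptic list. The synaptic median was then 0.020, against 0.023 for all tested genes, with camera's direction still down. For 103 genes followed through 14 alternatives, 353 of 420 values of called genes kept their direction and side of the threshold and 67 lost the call, 60 of them with a library left out; none reversed. Of 1022 values of genes not called, 151 passed, and 11 changed sign without passing. Those were Polr2a at 0.0068 with DESeq2 size factors, 0.0069 with upper quartile scaling, 0.0066 with DESeq2, 0.00078 without a filter and 0.031 with the replicate block with GC and length offsets, and, with a library left out, Polr2a from -0.056 to 0.044, Smc3 from -0.045 to 0.11, Rad21 from -0.013 to 0.12 and Top2b from -0.0077 to 0.083.

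Where the direction of a list reversed, the list was not called under that alternative. Microglia markers had a median of -0.031 with DESeq2 size factors, -0.028 with upper quartile scaling, -0.075 with limma-voom, -0.082 with block and offsets, -0.094 with the strict filter and -0.040 with fry; cohesin genes 0.045 with fry, whose direction was down; endothelial markers -0.55 without a filter; mitochondrially encoded genes -0.010 with block and offsets. With a library left out, medians ran from -0.020 to 0.091 for cohesin, -0.029 to 0.067 for break repair, -0.029 to 0.29 for cholesterol, -0.044 to 0.20 for ribosomal proteins (called by camera with all libraries), -0.36 to 0.11 for mitochondrially encoded genes, -0.12 to 0.15 for histones, -1.04 to 1.03 for oligodendrocyte, -0.20 to 0.20 for microglia and -0.27 to 0.15 for endothelial markers. The difference in the length measure ran from -0.070 to 0.029, in the mitochondrial share from -3.38 to 0.54 percentage points, and in the share of the 10 most abundant genes from -3.25 to 0.45. Break repair genes had a median of 0.0099 and a mean of -0.04, and microglia markers -0.04 and 0.16, with camera on the side of the mean. The cause was not tested.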

Other observations

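The lists of SRF and actin genes, of sodium and calcium channels with ryanodine receptors, and of nuclear-retained and detained-intron transcripts, the GC and length offsets and the comparison of noncoding scores between libraries were chosen after the calls had been seen, so they are not independent evidence, and most genes named from those lists lie outside the rule for naming genes. Genes of the serum response factor (SRF) and the actin cytoskeleton rose together within pairs: 21 of 27 were higher and 2 lower, with a median log2 change of 0.42. Tagln (0.67), Srf itself (0.73), Ccn2 (0.91), Thbs1 (0.80), Zyx (0.60) and Vcl (0.55), which builds focal adhesions, were among the rises, Actb went from 1616 to 2294 CPM, and the exceptions were Flna (-0.53) and Pdlim7 (-0.44). Tagln and Acta2 are also the 2 fibroblast and mural markers that rose within pairs, and 7 of 10 astrocyte markers and the progenitor markers Nes (0.37) and Vim (0.34) rose in the same fit, so these values do not say which cells the rises come from. Voltage-gated sodium and calcium channels and ryanodine receptors fell in 12 of 18 cases with 0 rises, among them Cacna1h (-0.69), Ryr3 (-0.87), Cacna1g (-0.61), Cacna1e (-0.55) and Scn3a (-0.51). Without the block 2 genes of the first list (Srf and Zyx) and 0 of the second passed in edgeR. Camera in the blocked fit gave unadjusted p of 2.03e-17 and 2.29e-14, and 0.093 and 0.072 with an estimated correlation.

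Noncoding RNAs were lower within pairs. Of 710 lincRNA, antisense and processed-transcript genes, 74 fell and 4 rose, against 1118 and 807 of 13428 protein-coding genes. Without the block their median was also -0.20, but none of them was called lower, and 1700016P03Rik was called higher. Meg3 went from 2833 ± 1081 to 1351 ± 720 CPM (mean ± SD, n = 3) and Miat from 408 ± 178 to 210 ± 112 CPM, falls that passed in edgeR within pairs and not without the block (adjusted p = 0.32 and 0.44). Of 38 nuclear-retained noncoding RNAs and transcripts with detained introns, 19 fell and 0 rose within pairs, including Ogt (-0.72), Clk1 (-0.66), Ccnl2 (-0.59) and Luc7l3 (-0.57). With GC and length offsets 18 fell and 1 rose. The nuclear-retained RNAs Malat1 (-0.18) and Neat1 (-0.03) did not pass within pairs (edgeR adjusted p = 0.21 and 0.88). Without the block 0 of the 38 passed. Camera with an estimated correlation gave an unadjusted p of 0.051 within pairs and 0.28 without the block. The median of the 710 genes, -0.20, lay below all 10000 random sets of protein-coding genes matched on expression (central range -0.04 to 0.0067), which argues against low expression, and stayed at -0.19 with GC and length offsets, with -0.18, -0.25 and -0.18 in the pairs, which argues against those trends. A difference in RNA preparation, such as the yield of nuclear RNA, cannot be told apart from an effect of NMDA: the mean level of these genes relative to all genes differed by -0.19, -0.28 and -0.17 log2 within pairs, and a preparation difference shared by the stimulated cultures would give the same sign in every pair. The same level differed by up to 0.29 between libraries of a group, but it followed the replicate number in both groups, so that spread does not decide. Faster splicing, export or decay of nuclear transcripts after stimulation is a candidate explanation that stays open and was not tested here.

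The 55 genes higher without the block had short gene bodies, as a hypothesis written before the result was seen had it. Their median was 8.75 kb, against a central range of 15.98 to 37.7 kb in 10000 random sets of tested genes matched on expression, and below all of them. Their exonic length, at a median of 3.92 kb, lay inside the central range of such sets (3.63 to 5.49 kb), towards its low end (percentile 9.8). A shorter mature transcript is thus neither shown nor excluded, and intron length was not tested by itself. Completion of short genes within the hour between stimulus and collection may contribute, and the data hold no later time to test it.

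Neighbours of those 55 genes were examined because the series concerns supercoiling, which can spread along the template. The 116 tested genes within 50 kb had a median log2 change within pairs of 0.054, above the central range of matched random sets (-0.05 to 0.04), though 11 were higher and 13 lower. The 26 downstream neighbours on the same strand stood 0.10 below the others (difference -0.10, central random range -0.14 to 0.10). That gives no sign of reads running past gene ends into genes of the same strand. The counting's strand setting is not given, and unstranded counting would also add such reads to opposite-strand genes among the others. The contrast therefore does not exclude them. With GC and length offsets the median was 0.055, inside the central random range of -0.02 to 0.07. The random median rose from -0.0043 to 0.022, and that of all tested genes from -0.0036 to 0.023. The neighbours did not rise with them, so their excess over other genes shrank. The neighbours stayed above the random median (percentile 92.3), so base composition and length, not corrected separately, could account for part of the small excess and are not shown to account for all of it.

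Other splits of the libraries bear on how the counts are read. Of the 10 splits into 3 and 3, the real one gave 63 genes and 60 at least 1.5-fold, 1 of 10 in each case, and the highest other gave 0; of 4 exchanges of labels within pairs, the real one gave 2051 and 467, 1 of 4 in each case, and the others 0. The splits and exchanges are too few for a share under 0.05. Every other split or exchange also sets part of any NMDA effect against itself. That part adds to the residual spread and works towards 0 calls. The contrast with 0 is therefore no separate support for the real counts. For gene lists, 3 of 10 splits gave as many camera calls as the real one: 12 lists were called for NMDA against control, and up to 15 in another split, of control 1, control 3 and NMDA 3 against the rest. That split parts only pair 1. The 3 other splits that part all 3 pairs, as the real one does, gave 9 to 11 lists and 0 genes. The first principal component took 48.3% of the variance, with control replicate 1 at 1 end (-29.5) and NMDA replicate 3 at the other (24.1).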
